A study of Drosophila melanogaster with 3 samples.

How the data were processed

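Whole Drosophila melanogaster embryos of both sexes, collected from 0 to 24 h of age, carried a transgene that stably expressed the basic helix-loop-helix (bHLH) transcription factor HLH54F with green fluorescent protein (GFP) joined to its C terminus. Chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated, and the recovered DNA was sequenced (ChIP-seq), per the labels. The labels disagree on the antibody: their descriptions name an antibody against GFP, which is followed here, and their antibody field names HLH54F. There were 3 biological replicates in 1 group, numbered as in the labels. The labels give no second group, so the comparisons were made between replicates, between strong and weaker peaks, between summits and their flanks, and between gene lists and matched random lists.

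Peak lists were used as deposited, each in 2 genome builds, dm6 and dm3. Per the text records deposited with the samples, each replicate's list was called on its own alignment against 1 control file, and a pooled list was called on the alignments of all 3 replicates against 1 control file. These 4 lists are relaxed and hold background, since they served as input to the irreproducible discovery rate (IDR) procedure, which keeps peaks that rank alike in replicates. The optimal IDR list, called the optimal peaks here, was derived by the authors from the replicate and pooled lists. The aligner, the peak caller, their versions and the IDR settings are not given in the sources used here. For each peak the authors deposited a signal value against the control, whose scaling is not given in the sources used here. It was used only to describe, rank and select peaks within a list. The deposited −log10 q-value of each peak was read but entered no test. The summit is the deposited offset from the start of the peak. Because all lists share the control and the pooled list contains every replicate, the optimal peaks are not independent of any replicate's list.

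In dm6 the optimal list held 4246 peaks, each also a line of the pooled list of 23689 peaks, and they were the 4246 pooled peaks of highest signal. A comparison of optimal with other pooled peaks was therefore a comparison of stronger with weaker peaks. The replicate lists held 30000, 30000 and 24914 peaks for replicates 1, 2 and 3. No interval was identical between any pair of replicates. Read totals were not used here, so the sequencing depth of each replicate is unknown. The 95% Wilson intervals of shares cover counting error over peaks only, and peaks are not independent replicates.

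Each replicate's list was reduced to its 4246 peaks of highest signal before lists were compared. A peak counted as found in a replicate when its summit lay inside one of these. The share found in every replicate was set against 1000 circular shifts of the optimal peaks along their chromosome arms (permutation test, one-sided). Pairwise overlap was the mean of both directions. Spearman's rho of ranks was computed across peaks, which are not independent, and has no p-value.

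Genes and transcription start sites (TSS) came from Ensembl release 115 (annotation BDGP6.54) and sequence from the release 6 genome, which has the coordinates of dm6. All peak ends lay inside the 6 arms. Start sites were the 5′ ends of all annotated transcripts other than transposable elements, a definition set after the files were seen and before any result. Summits were assigned to the first class that applied among within 500 bp of a TSS, 5′ UTR, coding exon, 3′ UTR, non-coding exon, intron and intergenic. Optimal peaks were compared with the 18639 pooled peaks that overlapped none of them by Fisher's exact test, two-sided. Values below 1e-300 are given as that bound.

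The 10 reverse-complement classes of CANNTG, the E-box that bHLH proteins bind, and GAGAG and CAGGTAG as controls were searched within 100 bp of each summit and in a window of equal length centred 600 bp away on a randomly chosen side. The windows were compared by the exact McNemar test, two-sided, with Benjamini-Hochberg adjustment over the 12 sequences. The 20 gene lists were fixed by textbook tissue or function. A gene counted as bound when an optimal summit lay in its body or up to 2 kb upstream. The number bound was compared with 10000 random lists of the same size drawn from the 9387 protein-coding genes with a pooled summit in that window, matched on 10 classes of window length (permutation test, two-sided, Benjamini-Hochberg over 20 lists). Of the listed symbols, 3 had no match in the annotation and were not analysed. Listed genes without a pooled summit in the window were also left out of the tests. Thus 12 of 22 neuroblast genes and 11 of 20 annotated bHLH genes were tested, and shares bound refer to tested genes only. There were 310 distinct listed genes, of which 37 stood in several lists.

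Genes were named by a fixed rule: HLH54F; the 20 optimal peaks of highest signal that lay in a top peak of all 3 replicates, each named by the protein-coding gene that holds its summit or else by the nearest TSS; every member of the caudal visceral mesoderm list; and up to 4 members of each other list with the strongest optimal peak. The groups, tests, lists, naming rule and main alternatives were set before the data were examined. The alternatives were another overlap rule, list length, TSS distance, window, background, threshold or build, and each replicate left out in turn. Further alternatives were added after seeing the data: E-boxes in distal peaks, in promoter peaks, in peaks matched for GC content and in the 500 strongest peaks; gene lists and the X share in distal peaks; and the promoter share of each replicate's own top peaks.

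The statistics were tested on simulated data. For the share found in every replicate, 60.8% of 4000 simulated peaks were found when 60% were planted, and 0 of 40 unrelated sets had a p under 0.05. In those sets the simulated replicate lists were unrelated to one another, unlike the real ones. Almost no peak could then lie in all of them, so the 0 of 40 was nearly fixed in advance. For gene lists, 2 of 40 unrelated lists among 9000 simulated genes had a raw p under 0.05 and 0 had an adjusted one. For site differences, a planted difference of 10 percentage points over 4000 peaks was recovered as 9.38, and 4 of 40 simulated sites with no difference had a p under 0.05. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.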

Results

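HLH54F is a bHLH transcription factor of the caudal visceral mesoderm, the founder tissue of the longitudinal gut muscles of the fly. Its genomic binding was profiled by ChIP-seq, with an antibody against the GFP tag per the labels' descriptions, in whole embryos of 0 to 24 h, in 3 biological replicates. The optimal list held 4246 peaks in dm6, with a median width of 420 bp and signal values, as the authors gave them, from 92.7 to 3344 (median 154). The same data in dm3 gave the authors 4587 peaks. Read depth per replicate is unknown, and no second condition was analysed here.

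The first question was which sites were bound in every replicate. The strongest peak lay at CG14100 on 3L (19590403 to 19590831), with its summit 103 bp from the TSS and a signal of 3344, and ranked 1, 2 and 1 in replicates 1, 2 and 3. Next came a peak in an intron of ush, which encodes the Friend-of-GATA cofactor of blood and dorsal tissues (2L, 480835 to 481324, signal 2934, ranks 3, 1 and 3). It was followed by a peak at the promoter of the UDP-galactose transporter gene Ugalt (X, 2703678 to 2704090, summit 45 bp from the TSS, signal 2776, ranks 2, 3 and 2). Chro, the gene of the chromatin protein Chromator, had a promoter peak on 3L (22878687 to 22879114) with a signal of 2051 and ranks of 4, 5 and 6. An intron of CG11050 on 2L held a peak of signal 1994.

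The remaining 15 of the 20 strongest shared peaks had signals from 1413 to 1824. Those within 500 bp of a TSS lay at ph-p (a Polycomb group gene, X), PNPase (a mitochondrial RNA exonuclease, 3R), px (2R), Tcs5 (3L), Shc (a signalling adaptor, 3L), CG1888 and mRpL41 (a mitochondrial ribosomal protein, both 2R), Pal1 (2R), CenG1A (2L), larp (an RNA-binding protein, 3R) and Art3 (an arginine methyltransferase, 3R). The peak named by CG4004 (X) was 5130 bp from that gene's TSS and within 500 bp of a TSS of a non-coding transcript. The peaks at Lk6 (a kinase, 3R), CG9663 (2L) and CG32772 (X) had their summits in introns. Ranks of these 20 peaks lay between 1 and 29 in every replicate. The widest spread was at CG32772, which ranked 18, 15 and 29 (20.7 ± 7.37, SD, n = 3).

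Of the 4246 optimal peaks, 2811 (66.2%, 95% Wilson interval 64.8 to 67.6%) had their summit in a top peak of all 3 replicates, 1004 in a pair of them, 417 in 1 and 14 in none. Circular shifts gave a mean of 0.638% and at most 1.11% (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). The optimal peaks were derived from these same replicates, so an overlap above random positions was fixed in advance. The p-value is therefore no evidence that the replicates agree. By rank, 99% of the peaks ranked 501 to 1000 and 2.44% of those ranked 4001 to 4246 were found in all replicates. Each replicate's list was itself cut at 4246 peaks, so low support at low ranks is expected from the cut, and with whole lists 96.6% of optimal peaks were found in all replicates. Replicates 1, 2 and 3 held 88.2%, 84.1% and 83.4% of the optimal peaks. Their whole relaxed lists held 99.6%, 99.3% and 97.7%.

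**Figure D1:**
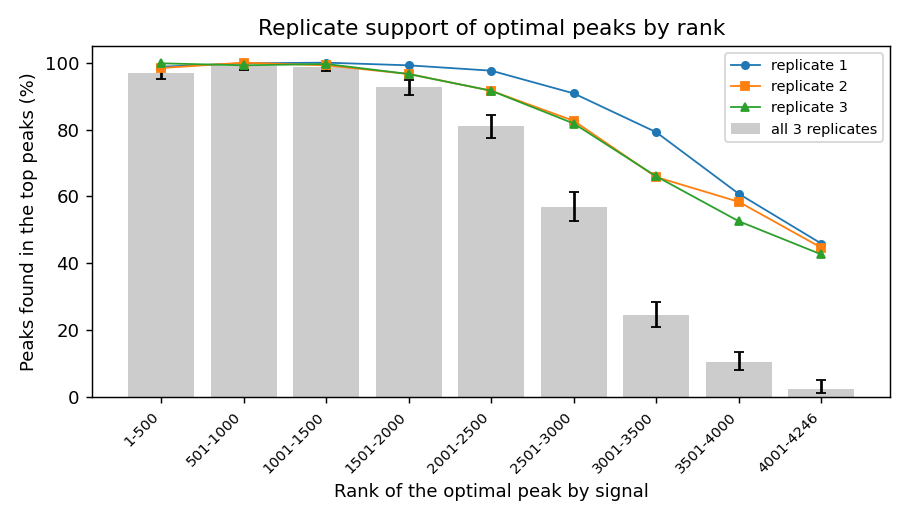
Share of optimal peaks (y axis, %) found among the top peaks of each replicate (lines) and of all 3 replicates (bars, with 95% Wilson intervals), by rank of signal in steps of 500 peaks (x axis). The share found in all 3 replicates was 97.0% in the first step and 2.44% in the last, where the replicate lists themselves ended.

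Pairs of replicates shared 78.0% (1 and 2), 77.2% (1 and 3) and 72.4% (2 and 3) of their top peaks, a mean of 75.9% ± 2.98 (SD over 3 pairs), against a mean of 1.18% and a maximum of 1.499% under the shifts. Among optimal peaks found in both lists of a pair, Spearman's rho of the ranks was 0.77 for replicates 1 and 2 (3216 peaks), 0.79 for 1 and 3 (3209 peaks) and 0.72 for 2 and 3 (3012 peaks). These values are across peaks, which are not independent replicates. With the whole relaxed lists, mean pairwise overlap fell to 44.8%.

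The second question was where in the genome the peaks lay. Optimal peaks lay mainly at promoters: 2586 of 4246 summits (60.9%, 59.4 to 62.4%) were within 500 bp of a TSS, against 5327 of 18639 (28.6%, 27.9 to 29.2%) of the weaker pooled peaks (odds ratio 3.89, Fisher's exact p below 1e-300). The replicates' own top peaks gave 60.0% ± 0.933 (SD, n = 3). Summits in coding exons made up 0.188% of optimal and 10.5% of weaker peaks (odds ratio 0.0161, Fisher's exact adjusted p = 1.31e-166 over 7 classes). Introns held 27.6% against 40.1% (odds ratio 0.572, exact adjusted p = 1.52e-52) and intergenic sequence 9.44% against 16.7% (odds ratio 0.519, adjusted p = 2.17e-35). The promoter share was 74.0% among the 500 strongest peaks and 52.4% among those ranked 4001 to 4246.

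**Figure D2:**
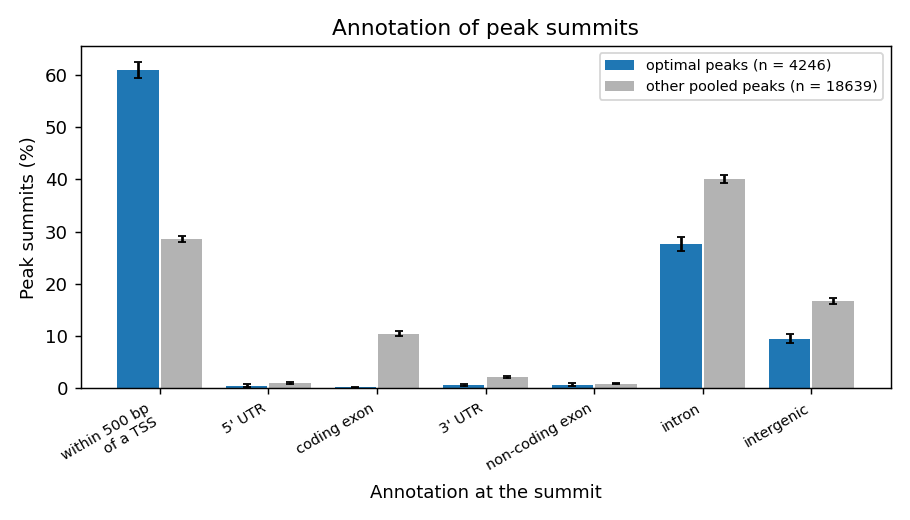
Share of peak summits (y axis, %) in each annotation class (x axis) for the 4246 optimal and the 18639 other pooled peaks, with 95% Wilson intervals. Optimal summits exceed the others only in the class within 500 bp of a TSS, 60.9% against 28.6%.

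Promoter summits lay just upstream of transcription. Relative to the nearest TSS the median position of the optimal ones was -77 bp, and 82.4% lay upstream, against -19 bp and 54.5% for weaker promoter peaks. Head-to-head pairs of protein-coding genes, transcribed away from each other with both TSS within 500 bp of the summit, held 972 of the 2586 optimal promoter summits (37.6%, 35.7 to 39.5%) and 744 of the 5327 weaker ones (14.0%, 13.1 to 14.9%; odds ratio 3.71, Fisher's exact p = 4.04e-120).

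Across the chromosome arms the X held 789 optimal peaks (18.6%, 17.4 to 19.8%), against 15.7% (15.2 to 16.3%) of weaker peaks (odds ratio 1.22, Fisher's exact p = 7.72e-06). The replicates' own top peaks gave 18.7% ± 1.23 (SD, n = 3), with a lowest value of 17.5%. Among these, peaks within 500 bp of a TSS had X shares of 16.5%, 15.9% and 17.2% in replicates 1, 2 and 3. The distal ones had 22.0%, 19.9% and 23.9%. Per megabase, optimal peaks numbered 33.5 on X, 34.2 on 2L, 31.6 on 2R, 29.4 on 3L, 31.5 on 3R and 13.4 on chromosome 4, which had 18 peaks. Weaker peaks numbered 125 per megabase on X and between 137 and 146 on 2L, 2R, 3L and 3R.

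Since bHLH proteins bind CANNTG, the next comparison asked whether these sequences stood out at the summits. Over all optimal peaks no class was more frequent within 100 bp of summits than in the flanks after adjustment over 12 sequences. CAGCTG was present at 11.2% of summits and 10.6% of flanks, a difference of 0.589 percentage points (95% interval -0.713 to 1.89, exact McNemar adjusted p = 0.502), and CATATG at 7.37% and 6.38% (adjusted p = 0.141). Over the replicates' own top peaks the CAGCTG difference was 0.981 ± 0.483 points (SD, n = 3). With a window of 200 bp each side, CAGCTG was in excess by 2.59 points (exact adjusted p = 0.00912).

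Promoter and distal peaks differed in CAGCTG, in a split made after seeing the data. In the 2586 peaks within 500 bp of a TSS it was present at 14.2% of summits and 11.1% of flanks, an excess of 3.09 points (1.28 to 4.91, exact adjusted p = 0.0040). It was the single class in excess there, and 4 were less frequent at promoter summits than in flanks. CACCTG differed by -6.15 points (-7.70 to -4.60, exact adjusted p = 1.42e-13), CAACTG by -2.13, and CAAGTG and CAGATG by -2.09 each. Both controls were also less frequent there, GAGAG by -4.10 points and CAGGTAG by -0.928 (exact McNemar adjusted p = 0.00196 and 0.00801). CACCTG was present at 6.30% of promoter and 5.90% of distal summits, and at 12.5% of promoter and 7.17% of distal flanks. Its larger deficit at promoter peaks thus lay in the flanks more than in the summits. In the 1660 distal peaks the CAGCTG difference was -1.57 points (-3.30 to 0.167). Among peaks with CAGCTG in a single window, it lay at the summit in 329 and the flank in 249 promoter peaks, and in 95 and 121 distal peaks (odds ratio 1.68, Fisher's exact p = 0.00136).

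Over all optimal peaks, CACCTG, CACATG, CAGATG and CAACTG were less frequent at summits than in flanks. CACCTG occurred at 6.15% of summits and 9.73% of flanks (difference -3.58 points, -4.73 to -2.43, exact adjusted p = 1.69e-08), and its difference over the replicates was -3.71 ± 0.219 points (SD, n = 3). Over the replicates CACATG differed by -2.12 ± 0.308, CAACTG by -1.73 ± 0.311 and CAGATG by -1.19 ± 0.584 points (SD, n = 3). CAGATG was past the threshold in replicate 2 only, and CAACTG in replicates 2 and 3 only. The control sequence GAGAG was also less frequent, by -2.61 points (exact adjusted p = 0.0106), and CAGGTAG did not differ past the threshold (adjusted p = 0.141). In the own top peaks of replicates 2 and 3 CAGGTAG was less frequent, by -0.824 and -0.659 points (exact McNemar adjusted p = 0.00196 and 0.0159). It was not called in replicate 1. Summit windows had a GC content of 37.4% and flanks of 44.0%. In 586 peaks whose summit and flank differed by at most 2 percentage points of GC, a subset chosen after seeing the data, no CANNTG class was past the threshold. Of the 4 classes, CACCTG differed there by -0.171 points (-2.78 to 2.44, an interval that excludes its -3.58 over all peaks), CAACTG by 0.171 (-3.57 to 3.91), CAGATG by -0.853 (-3.83 to 2.12) and CACATG by -2.73 (-6.26 to 0.802). The intervals of CAACTG, CAGATG and CACATG include their values over all peaks.

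**Figure D3:**
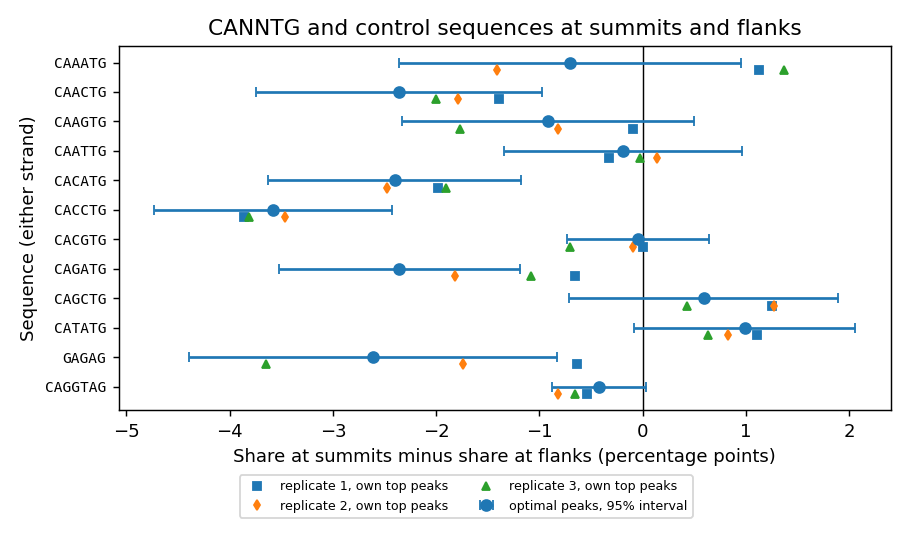
Share of windows holding each sequence at summits minus flanks (x axis, percentage points), for the 10 CANNTG classes and 2 controls (y axis). Circles with 95% intervals are the 4246 optimal peaks and smaller marks the top peaks of each replicate; CACCTG lies at -3.58 points and the interval of CAGCTG includes 0.

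At the HLH54F gene itself (2R, 17757405 to 17760517) no optimal peak was found. Of its 3 pooled peaks the strongest lay at the promoter (17757095 to 17757514) with a signal of 63.0, below the lowest optimal signal of 92.7, and ranked 13439, 5297 and 22692 in replicates 1, 2 and 3. Of the other caudal visceral mesoderm genes, zfh1, a zinc-finger factor of the mesoderm, had the strongest peak, in an intron (3R, 30781648 to 30781889, signal 462, ranks 311, 260 and 304). The integrin subunit gene mys followed with a promoter peak (X, 8061500 to 8061693, signal 303, ranks 816, 1034 and 465). The FGF gene ths held 3 optimal peaks, the strongest in an intron (signal 232), and the integrin gene mew held 4 (signal 164).

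Weaker optimal peaks lay at the integrin gene if (149), beat-IIa (94.6) and the integrin gene scb (93.4). The peak counted for the FGF pathway adaptor gene stumps (signal 160) lay upstream of it, in an intron of CG7987, 1908 bp from the TSS of stumps and 578 bp from that of CG7987. The strongest peaks of stumps, beat-IIa and scb were not in the top peaks of every replicate; scb, for example, ranked 4250, 5021 and 4744. No optimal peak lay at croc, at the FGF receptor gene htl (best pooled signal 87.6), at pyr, at beat-IIb, at the laminin genes LanA, LanB1, LanB2 and wb, or at byn. In all, 8 of the 18 caudal visceral mesoderm genes were bound, against 9.18 ± 2.11 (SD) in matched random lists (two-sided permutation adjusted p = 0.867). Counted within 1 kb of a TSS, 3 of 16 were bound (mys, if and scb), against 7.26 ± 1.97 (SD), a ratio of 0.413 instead of 0.872 (raw permutation p = 0.0492, adjusted p = 0.177). Under that rule 17 of the 20 lists had a lower ratio, 11 of them by over 1.5 times. Chromatin of whole embryos pooled over 0 to 24 h does not separate tissues. The list results therefore cannot show binding within the caudal visceral mesoderm itself.

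Ribosomal protein genes were the single list of 20 whose number of bound genes differed from chance. Of 40 genes 30 were bound, against 16.8 ± 3.06 (SD) in matched lists (ratio 1.79, two-sided permutation p = 0.0002, the smallest that 10000 lists can give, adjusted p = 0.0040). The strongest were RpS27 (3R, signal 875, 21 bp from a TSS), RpL7 (2L, 812, 31 bp), RpL14 (3L, 569, 40 bp) and RpS20 (3R, 519, 150 bp from the nearest TSS, that of a neighbour). Among all genes with a pooled summit, 4273 of 9387 (45.5%) were bound. With peaks over 500 bp from a TSS only, 0 of 15 ribosomal protein genes were bound against 1.13 ± 1.02 (SD) in matched lists (raw permutation p = 0.612), and no list passed.

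Muscle and mesoderm lists did not differ from chance past the threshold; p-values of lists are adjusted over the 20 lists unless named raw, and the value beside a gene is the signal of its strongest peak. Of 119 bound genes in the lists, 42 had the summit of that peak nearer to another gene's TSS, 17 of them outside the gene itself. Among the genes named below, with neighbours named after the values were seen, those 17 include mbc (at Nup98-96), nSyb (at Bgb), Pxn (at MEP-1), Tdrd3 (in an intron of bmm), E(spl)m3-HLH (at a non-coding gene), Mef2 and gbb. Other summits lay inside the named gene but within 500 bp of another gene's TSS. Examples are kirre (157 bp from Syx4), insc (131 bp from sktl), vas (56 bp from vig), ChAT (300 bp from a non-coding gene) and mwh (416 bp from CG9119). The ush summit lay 4840 bp from its own TSS and 1372 bp from that of cbt. In the trunk visceral mesoderm list 8 of 15 genes were bound (permutation p = 1). Its strongest peak, counted for the myogenic factor gene Mef2, was the Pal1 promoter peak of signal 1583, followed by kirre (370, with 11 optimal peaks), org-1 (228) and Fas3 (195). Somatic muscle genes had 6 of 18 bound (mbc 523, rols 146, Poxm 138 and nau 100.1; permutation p = 0.485) and contractile genes 5 of 19 (Msp300 819, sls 492, TpnC47D 114 and Zasp52 102.2; permutation p = 0.330). Of heart genes 2 of 12 were bound, Mef2 and tin (117), with a raw p of 0.0408 and an adjusted permutation p of 0.272. When a summit counted only for the protein-coding gene of the nearest TSS, at any distance, 6 of 13 heart genes were bound against 5.51 ± 1.77 (SD). The ratio was 1.09 instead of 0.337. That rule has no limit of 2 kb upstream, so these ratios do not measure the same thing.

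Neither gut list passed the threshold. Hindgut and posterior patterning had 7 of 10 genes bound (permutation p = 0.699), the strongest being otp (683, in a coding exon), bowl (371), fkh (274) and raw (197). In the midgut list Ubx and dpp (both signal 140) were the 2 bound genes of 9 (permutation p = 0.461). The bHLH list had 3 of 11 genes bound, da (194), which encodes the common partner of class II bHLH proteins, nau and emc (98.6), with an adjusted permutation p of 0.624.

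Among the lists of other tissues, neuroblast genes had 2 of 12 bound, grh (281) and insc (154), with a raw p of 0.0368 and an adjusted permutation p of 0.272. Counted within 1 kb of a TSS this list had 0 of 11 bound, against 5.04 ± 1.63 (SD), and passed (permutation p = 0.0180 after adjustment). Neuronal genes had 5 of 17 bound (elav 634, nSyb 273, ChAT 245 and nAChRalpha6 112; permutation p = 0.368), and glial genes 5 of 8 (moody 728, pnt 234, loco 155 and nrv2 110; permutation p = 0.867). Blood cell genes had 3 of 10 bound, ush (2934, with 13 optimal peaks), Pxn (174) and lz (98.95), with an adjusted permutation p of 0.624. Fat body genes had 2 of 7 (Adh 128 and Idgf6 99.96; permutation p = 0.843), epidermal genes 6 of 12 (grh 281, crb 217, baz 213 and mwh 189; permutation p = 1) and tracheal genes 3 of 10 (rib 148, peb 111 and bnl 99.95; permutation p = 0.624).

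Germline genes had 6 of 10 bound (Tdrd3 410, ovo 185, piwi 153 and vas 117; permutation p = 0.852). Genes of Notch signalling had 8 of 14 bound (mam 413, N 323, neur 295 and E(spl)m3-HLH 242; permutation p = 0.852) and Hox genes 3 of 8 (Antp 206, Ubx 140 and Abd-B 113; permutation p = 0.843). Receptor and ligand genes had 17 of 30 bound (gbb 1345, spi 765, Krn 342 and fz 306; permutation p = 0.852). Counted within 1 kb of a TSS, 6 of 27 were bound against 12.6 ± 2.56 (SD), a ratio of 0.478 instead of 1.10 (raw permutation p = 0.0180, adjusted p = 0.120). The summit counted for gbb lay 73 bp from the TSS of a non-coding antisense gene and 102 bp from that of eIF6, the nearest of a protein-coding gene (named after the values were seen), since a summit inside overlapping windows counted for each gene.

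**Figure D4:**
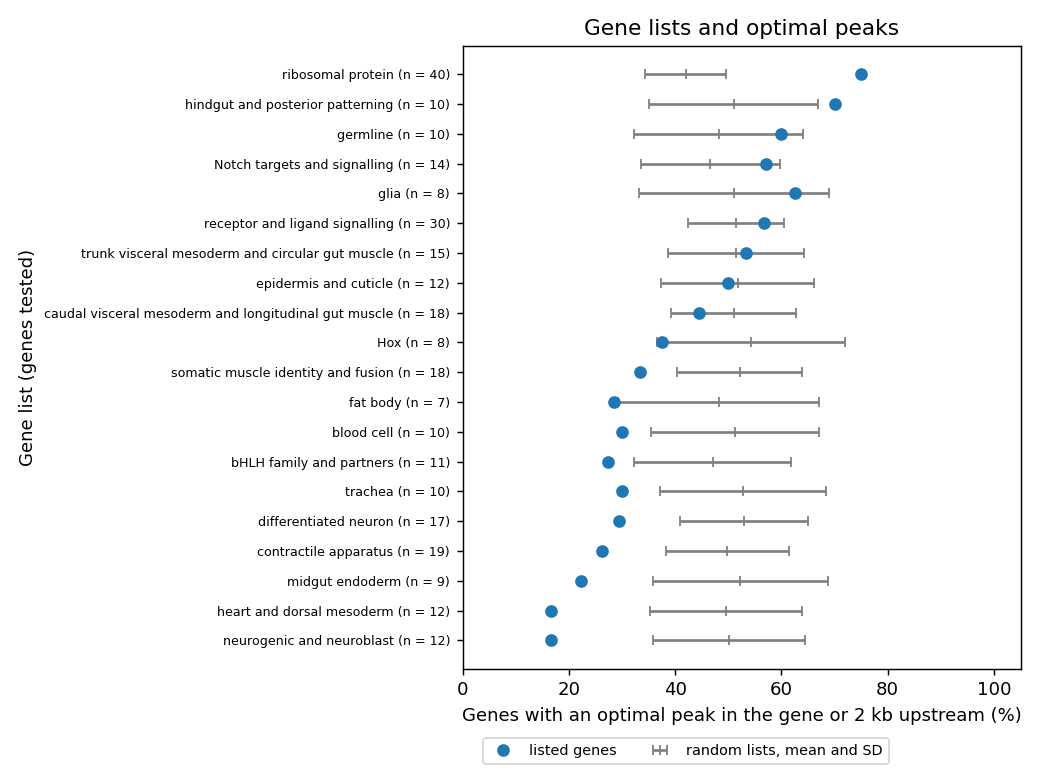
Share of genes with an optimal peak in the body or 2 kb upstream (x axis, %) for each of 20 gene lists (y axis, with the number of genes tested). Circles are the listed genes and grey bars the mean and SD of matched random lists; ribosomal protein genes stand at 75.0% against 42.0%.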

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

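All tests on distal, promoter, GC-matched or strongest peaks below were chosen after seeing the data. Of the alternative values of the main results, 46 counted as unchanged and 13 moved. Unchanged values kept their direction and side of the threshold, stayed within the spread or, for counts, changed by at most 1.5 times. The share found in every replicate ranged from 52.1% to 96.6% over 5 alternatives and from 70.9% to 75.7% with a replicate left out. Each setting gave the smallest p its shifts allow, an outcome fixed in advance because the optimal peaks were derived from these replicates. All these values count among the 46 unchanged, and for them that label carries no information on robustness. The rules of 1 bp and of 50% reciprocal overlap used 200 shifts. Pairwise overlap moved to 71.1% with 50% reciprocal overlap and to 44.8% with whole lists, and ranged from 72.4% to 78.0% with a replicate left out. Rank agreement moved to 0.72 with whole lists and ranged from 0.72 to 0.79. The promoter share ranged from 46.8% to 70.3% and the X share from 18.5% to 21.9%, each past the threshold. The number of CANNTG classes less frequent at summits, 4, was 4 in promoter peaks, 6 against other pooled summits, 0 in distal peaks, 0 in GC-matched peaks and 0 in the 500 strongest. Some differences kept their size where calls were lost: CACCTG was -4.80 points in the 500 strongest, and CACATG -2.23 in distal and -2.73 in GC-matched peaks; 1 class was in excess with a window of 200 bp and 1 in promoter peaks. GAGAG turned to 0.0471 points with that window and to 1.54 points in GC-matched peaks, where CAACTG turned to 0.171 points. Lists past the threshold numbered 2 within 1 kb of a TSS and 0 in distal peaks, where the ribosomal ratio was 0 with 1.13 of 15 genes expected. The stricter list holds 2123 peaks by construction. The cause of the other changes was not tested, beyond the smaller number of peaks in each subset. Of 228 values of single sites and lists, 17 site differences and 17 list ratios changed side without a call in either setting. Besides these, 17 site differences lost their call, 6 gained a call and 3 reversed. Among list ratios 1 gained a call and 1 reversed. The promoter, sequence, X and gene-list results rest on the pooled calls and have no value without a replicate. No paired analysis was possible because there is 1 group. Unknown depth limits all comparisons of list sizes.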

Other observations

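The tests of E-boxes in subsets of peaks, of 8-base sequences, of ribosomal protein genes among genes with promoter peaks and of the X in distal peaks were chosen only after the data were seen. In a search for all 8-base sequences within 50 bp of summits, 42 were more frequent at summits than at flanks on 2L, 2R and 4 (exact McNemar test, adjusted over 32896 classes), and 39 of these were also in excess on 3L, 3R and X. Many are rich in A and T. Of those with 3 or more G or C, 20 of 21 held on the other arms, among them ATCGATAG (103 peaks at the summit only and 12 at the flank only), CAACACTG (77 and 8) and GGTCACAC (42 and 12). Several of the 20 share a core, such as ATCGAT or AACACT, so they are not 20 separate elements. Of the 42 sequences 1, AACAGCTG, holds a CANNTG, and it did not hold on the other arms (43 and 30 peaks, exact adjusted p = 0.168). Among peaks over 500 bp from a TSS, of which 613 lay on the first arms, 0 sequences passed there. The full set of peaks had been looked through for such sequences earlier, so the arms are not fully independent.

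All 20 held sequences with 3 or more G or C were more frequent at promoter than at distal optimal summits and, by 1.26 to 3.54 times, at optimal than at weaker promoter summits (Fisher's exact tests, adjusted p under 0.05, on peaks that also served to find them). TATCGATA, the core of the promoter element bound by DREF in background knowledge, was present at 9.20% (8.15 to 10.4%) of optimal and 5.71% (5.12 to 6.36%) of weaker promoter peaks, a ratio of 1.61 (Fisher's exact p = 1.86e-08), and at 8.98% ± 0.228 in the replicates' own top promoter peaks (SD, n = 3). GGTCACAC was present at 5.92% and 4.69%, a ratio of 1.26 (Fisher's exact p = 0.0220), and CAGCTG at 14.2% and 11.9% (Fisher's exact p = 0.00434). In the replicates' own top promoter peaks GGTCACAC was at 5.24% ± 0.0824 and CAGCTG at 13.8% ± 0.923 (SD, n = 3), with 12.7% in replicate 3. At distal peaks CAGCTG went the other way, at 6.51% of optimal and 9.93% of weaker summits, a ratio of 0.655 (Fisher's exact p = 3.18e-06). These distal sets differed in annotation, with 8 optimal and 1952 weaker summits in coding exons. They were not matched for annotation or sequence composition, so this ratio cannot show that strong distal sites lack CAGCTG. Density of CAGCTG around promoter peaks was 0.719 sites per kb (counting error 0.0527) within 50 bp of the summit, 0.858 (0.0576) from 50 to 100 bp and 0.604 (0.0197) from 500 to 800 bp. Around distal peaks it was 0.349 (0.0459) within 50 bp and 0.468 (0.0217) from 500 to 800 bp. AGATGGCG, chosen after it was seen, was present at 2.29% of 1660 distal optimal summits and 0.909% of 13312 weaker ones (Fisher's exact p = 4.82e-06), which does not pass a correction for all 32896 classes (p = 0.158).

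For the lack of an E-box excess over all peaks, one of CAGCTG hidden at distal peaks was not seen, with a difference of -1.57 points there (-3.30 to 0.167). Summits and flanks were not matched for GC in that comparison, so it cannot decide the question. An excess of another class at distal peaks also stays open (CATATG, with an upper bound of 3.06). An excess of CAGCTG hidden by weak peaks was not seen either, with a difference of -2.40 points in the 500 strongest (-6.11 to 1.31). That interval includes the 0.589 points found over all peaks, and GC was not matched, so it cannot decide this. One of another class stays open, since no class was called there in either direction and upper bounds reached 5.90 (CAAATG). A promoter excess of CAGCTG hidden by distal peaks stays open, because the value that would support it, 3.09 points at promoter peaks (1.28 to 4.91), is also the one that prompted it, and CACCTG was lower there by -6.15 points. The lower GC content of summits may contribute and stays open: in the 586 GC-matched peaks CAGCTG was 4.27 points more frequent at summits (0.9903 to 7.54), with a raw exact p of 0.0144 and an adjusted p of 0.158. A source of anti-GFP signal other than sequence-specific binding by the tagged protein could also give peaks without E-boxes, and with 20 held sequences it cannot be told apart from such binding, since all arms had been searched earlier and no embryo without the tag was analysed here.

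Binding at ribosomal protein genes was weighed against the density of their neighbourhood and against promoter binding in general. When a summit counted only for the protein-coding gene of the nearest TSS, at any distance, 25 of 39 were bound against 12.3, a ratio of 2.03 (permutation adjusted p = 0.0040), which argues against neighbouring promoters. Among the 7025 genes with a pooled peak within 500 bp of a TSS, 28 of 40 were bound against 18.3 ± 3.16 (SD), a ratio of 1.53 (permutation p = 0.0022), which argues against a general promoter excess. Open explanations, such as high transcription of these genes, were not tested.

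The higher X share was weighed against promoter content. Among peaks over 500 bp from a TSS, the X held 21.9% of 1660 optimal and 15.3% of 13312 weaker peaks, an odds ratio of 1.55 (Fisher's exact p = 4.63e-11), which argues against an excess carried by X promoters. In the replicates' own top distal peaks the share was 22.0%, 19.9% and 23.9%, and in their top promoter peaks 16.5%, 15.9% and 17.2%. The excess is thus shown for distal peaks, and optimal and weaker promoter peaks were not compared. The dosage of the X in embryos of mixed sex was not tested. No biological explanation of any of these patterns was tested, since there is 1 group.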
